A study of Mus musculus with 16 samples.

How the data were processed

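RNA from whole tibialis anterior muscle of mice at postnatal day 30 was sequenced in 16 libraries, 4 from each of Control, miR-133b-/-, mdx and mdx/miR-133b-/- animals. RNA was extracted with the Aurum kit of Bio-Rad with a DNase step, per the labels' protocols. Reads were aligned with HISAT2 to GRCm38 and counted per gene with HTSeq, per the submitters' processing notes; their versions and settings, and whether counting used strand, are not given in the sources used here. Libraries were assigned to groups by the code in each sample's title. The description field names the code of another sample for 14 of the 16, and grouping by it was run as a check of the labels. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

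The deposited table gives a signal value per gene and library for 831 Ensembl genes. The authors scaled whole read counts by 1 factor per library (0.459 to 1), per the values themselves: dividing by the factor gave a whole number, to within 0.001 read, for 100% of the values. Reads in the listed genes numbered from 2356990 to 6000033 per library, and the total depth is unknown. All 831 identifiers matched GENCODE M21, the source of symbols and GRCm38 coordinates; 788 are protein coding, 45 are predicted or pseudogene models, 7 are antisense and 9 are mitochondrially encoded. Because strand use is unknown, values of antisense and overlapping genes are uncertain, as are those of genes with near-identical copies. No library pair within a group looked like 1 library counted again, since the chi-square per degree of freedom was 38.7 or more in all 24 pairs.

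The listed genes are a selection. The ratio of the mdx/miR-133b-/- mean to the miR-133b-/- mean is at least 1.72-fold, either way, in each of them, and the lowest mean over the 16 libraries is 50.1. Comparisons that use either group share the libraries of that selection, and only mdx against Control uses none of them.

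The test planned before the data were examined was a count model on unscaled reads. The values turned out to be scaled, on a short selected list from which library sizes and composition cannot be estimated, so the test was changed. Log2(value + 1) was fitted with limma, with 1 mean per group over all 16 libraries, empirical Bayes moderation with a variance trend, and Benjamini-Hochberg adjustment over the 831 genes at 0.05, with no filter. Fold changes are on that log2 scale, which understates the change of low genes. The 5 comparisons of 2 groups and the interaction, the mdx/miR-133b-/- to mdx difference minus the miR-133b-/- to Control difference, came from the same fit. limma-voom on the recovered reads was run as an alternative.

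Gene lists were fixed before the data were examined: 28 lists of muscle, matrix, immune, metabolic and other cell-type genes. Of these, 17 have listed members and 14 have at least 2, which were tested with camera at a preset correlation of 0.01 between genes, and again with the correlation estimated, adjusted over the lists of each comparison. The other 11 were not analysed here, having no listed member: satellite cell, lymphocyte, neutrophil, cell cycle, muscle growth signalling, pericyte and smooth muscle, adipocyte, Schwann cell, erythrocyte, immediate early and heat shock, and sex-linked genes. Matches to the seed of miR-133b (positions 2 to 8) were searched in the annotated 3' UTRs of 780 genes and found in 89, of which 25 had an 8mer match.

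Genes were named by a rule. Dmd, Utrn and genes of the miR-133b locus were to be given wherever listed. In mdx against Control, miR-133b-/- against Control and mdx/miR-133b-/- against mdx, the 4 largest rises and 4 largest falls were taken among genes that passed, whose groups did not overlap and whose mean scaled value over both groups was at least 50, leaving out predicted models; that minimum replaced a planned one on depth-scaled reads. In each list with 1 to 4 genes called the one with the smallest p was taken, and with 5 or more the 2 smallest. The remaining comparisons and the interaction took the 3 largest in each direction, of which 1 gene is not reported here. Where fewer than 3 genes passed, the 3 smallest p-values in each direction are given as not passing. Other list members are named by symbol or value.

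The procedure was tested on simulated data for 831 genes in 5 runs, with 200 genes changed per run in mdx against Control. Each gene had its mean over all 16 libraries and its spread pooled over the 4 groups. The test recovered 6.40% of 1.25-fold, 26.4% of 1.5-fold, 66.4% of 2-fold and 85.2% of 3-fold changes, and 3.76% of its calls were false. Genes were simulated independently, with no GC or length trend and no selection, so the share of false calls may be higher in the real libraries. Alternatives covered the scaling factors, pseudocounts of 0.5 and 10, no variance trend, a minimum mean of 100, fits on the libraries of 2 groups, a replicate block, removal of each library's linear trend with GC content and transcript length, and leaving out each library in turn. GC content and length are those of the longest annotated transcript. The number of genes called was set against all 35 splits of the 8 libraries, or against 100 draws for the interaction. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.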

Results

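Gene expression was measured by RNA sequencing in whole tibialis anterior muscle of mice at postnatal day 30. The 16 libraries form 4 groups of 4: Control, miR-133b-/-, mdx and mdx/miR-133b-/-, the last carrying both changes. The mdx mouse has a mutation in Dmd, the dystrophin gene, and is a model of Duchenne muscular dystrophy; miR-133b is a microRNA of skeletal muscle. The 4 groups allow the loss of miR-133b to be read both in dystrophic muscle and in muscle with dystrophin. The values are read counts that the authors scaled by 1 factor per library, given for 831 genes. Reads in these genes numbered 3770061 ± 477378 per library in Control (SD, n = 4), 3953472 ± 1432266 in miR-133b-/-, 3283120.0 ± 353239 in mdx and 2675254 ± 460419 in mdx/miR-133b-/-. The full depth of the libraries is unknown, and the reads in listed genes ranged from 2356990 to 6000033.

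The listed genes are not a cross-section of the transcriptome. In every one of them the means of mdx/miR-133b-/- and miR-133b-/- differed by at least 1.72-fold, while the smallest difference in each other comparison was at most 1.02-fold. Counts of changed genes below are therefore shares of a selected list. Dmd, its relative Utrn and the genes of the miR-133b locus are not listed and were not analysed here, so no listed gene checks the genotypes. Along the first principal component (71.8% of the variance of the listed genes) the 8 libraries with the mdx mutation lay between 13.9 and 29.4, and the other 8 between -31.8 and -14.0. The separation of mdx/miR-133b-/- from miR-133b-/- follows from how the listed genes differ, so it does not check the labels. Of the groups outside that difference, mdx lay at 14.0 to 20.1 and Control at -20.0 to -14.0. The median SD of a gene between replicates, on the log2 scale, was 0.27 in Control, 0.43 in miR-133b-/-, 0.21 in mdx and 0.38 in mdx/miR-133b-/-.

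Comparing mdx with Control shows what accompanied the loss of dystrophin. Listed regenerating fibre genes rose together: all 7 were higher in mdx, with a median log2 fold change of 2.92. Their fixed list holds 15 genes, and the rest are not listed and were not tested. Other fixed lists hold more genes than are listed: 20 macrophage, 20 extracellular matrix, 12 antigen presentation, 10 slow fibre and 10 tendon genes. The listed genes all differ between mdx/miR-133b-/- and miR-133b-/-, a difference that includes mdx. Counts by list for mdx against Control therefore favour genes that respond to mdx, and do not describe whole lists. Myh3, the embryonic myosin heavy chain (chromosome 11, 67078300 to 67102291), went from 45.7 ± 12.3 scaled reads in Control to 2533 ± 1588 in mdx (SD, n = 4 each). That is a 46.5-fold rise, or 5.54 on the log2 scale (SE 0.62, adjusted p = 6.2e-06). Myl4, a myosin light chain of embryonic muscle, rose 13.3-fold, from 38.2 ± 7.15 to 539.9 ± 179 scaled reads. The other listed members were Myog, Mymk, Tnnt2, Igf2 and Chrng. Among them are a myogenic transcription factor, the fusion protein myomaker and the fetal subunit of the acetylcholine receptor.

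Slow-fibre genes rose as well, in all 4 listed members (Tnnt1, Tnni1, Atp2a2 and Casq2), by a median of 3.26-fold. Tnni1, slow troponin I, rose by 4.00 on the log2 scale (SE 0.62), from 13.7 ± 7.29 to 215 ± 96.0 scaled reads. Of the 4 listed fast-fibre genes, Myh4 and Ckm, the muscle creatine kinase, fell. Actn3 (log2 fold change -0.52) and Pvalb (-0.22) did not pass. Among 5 listed genes of the neuromuscular junction, Chrna1, Chrnd, Ncam1 and Runx1 rose, Runx1 by 5.27-fold (log2 2.40, SE 0.33), while Musk stood at 0.30 and did not pass. Both listed genes of the muscle atrophy list rose; Cdkn1a, a cell cycle inhibitor, rose 2.84-fold (SE 0.37 on the log2 scale). In the dystrophin complex list, Lama2, a laminin chain of the fibre's basement membrane, rose 1.45-fold (SE 0.17 on the log2 scale), and Sntb1 (0.40) and Nos1 (-0.16) did not pass.

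Genes of macrophages and of antigen presentation rose as well. Of 13 listed monocyte and macrophage genes 12 rose, by a list median of 5.83-fold; the exception was Mrc1 at 0.33 on the log2 scale (adjusted p = 0.234). Adgre1, the gene of the macrophage marker F4/80, rose 5.66-fold, from 53.3 ± 17.7 to 296 ± 36 scaled reads, and C1qb, a complement component, rose 4.72-fold. All 5 listed genes of antigen presentation and complement rose, including Cd74 (5.58-fold) and H2-Eb1 (5.54-fold), both of the class II pathway. The only listed member of the interferon response list, Oas2, rose 3.07-fold. By the rule for naming single genes, the largest rises after Myh3 were Atp6v0d2, a subunit of the vacuolar proton pump (4.88 on the log2 scale, SE 0.91), Itgax, the integrin CD11c (4.31, SE 0.77), and Ms4a7 (4.10, SE 0.58).

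Connective tissue genes moved in the same direction. All 9 listed members of the extracellular matrix list rose (Col3a1, Col5a2, Fn1, Postn, Tnc, Lox, Loxl1, Bgn and Timp1), by a median of 2.45-fold. Postn, periostin, went from 872 ± 312 to 4978 ± 429 scaled reads, and Tnc, tenascin C, rose 4.27-fold. Both listed markers of fibro-adipogenic progenitors rose, Pdgfra by 2.46-fold and Lum. Both tendon genes also rose, Thbs4 by 4.57-fold and Col12a1. The only listed member of the endothelial list, Flt1, a receptor for vascular growth factors, fell by 0.75 on the log2 scale (SE 0.19).

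Mitochondrially encoded transcripts took 33.7% ± 3.89 of the listed reads in Control and 25.2% ± 1.76 in mdx (SD, n = 4 each). Hk2, a hexokinase, fell by 0.87 on the log2 scale (SE 0.24) and Aldoa also fell, while Pfkm (-0.24) did not pass. Ndufs1, of respiratory complex I, fell by 0.42 (SE 0.16), as did Cox5a, of complex IV, whereas Ndufa9 and Atp5a1 did not pass. Cpt2, the only listed member of the fatty acid use list, stood at -0.48 with an adjusted p of 0.0563. The largest falls by the naming rule were in Ces1d, a carboxylesterase (-2.95, SE 0.54), Dach2, a transcriptional regulator (-2.64, SE 0.32), Ciart, a circadian repressor (-1.96, SE 0.48), and Slc1a1, a glutamate transporter (-1.91, SE 0.31). Of 4 listed genes named in earlier work as miR-133 targets, Runx2 rose 3.78-fold and Klf15 fell by 0.95, while Gli3 and Egfr did not pass.

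**Figure D1:**
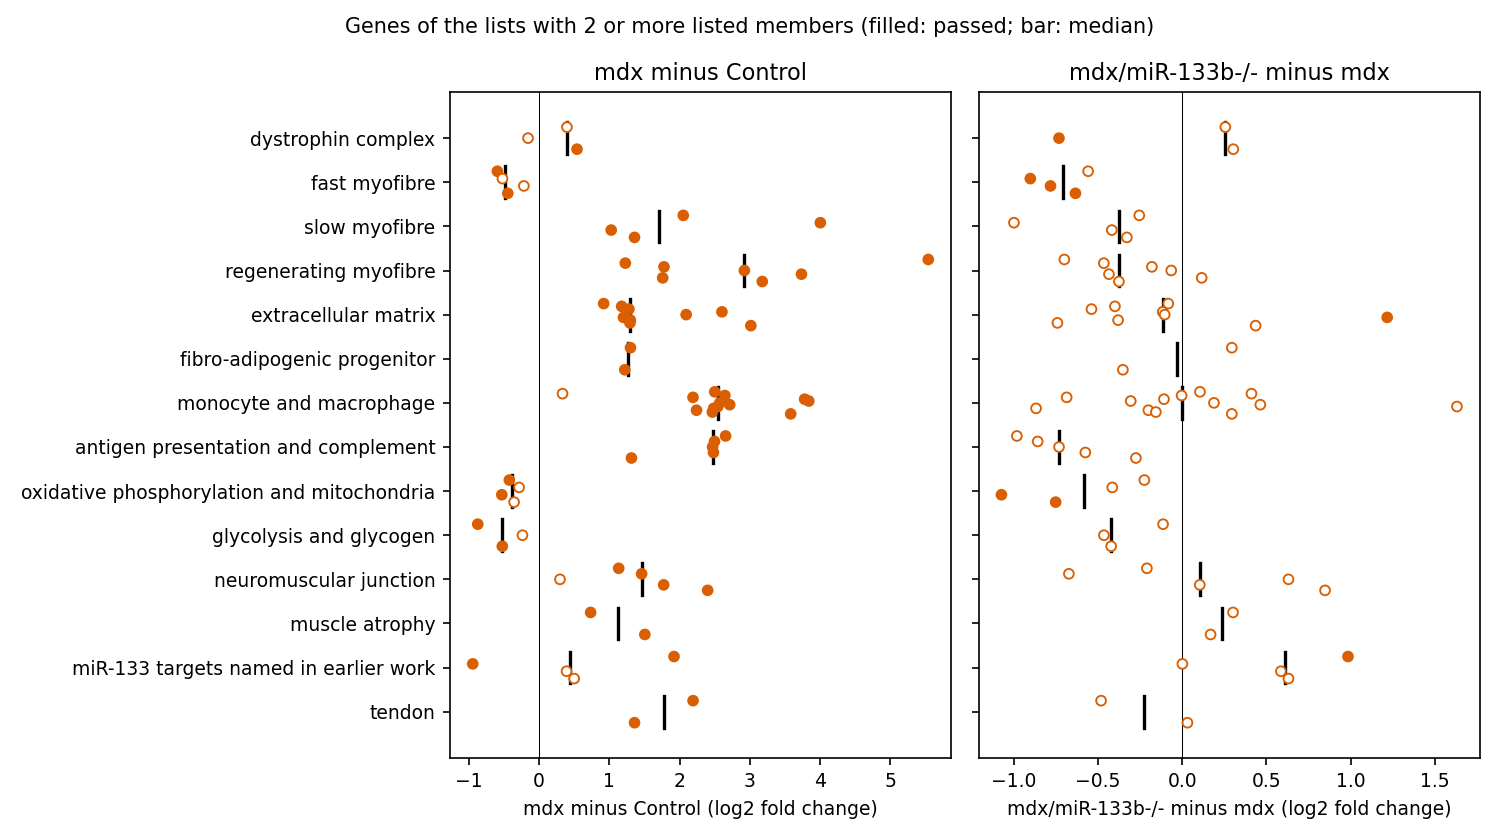
Log2 fold changes (horizontal axes) of the genes in each fixed list with 2 or more listed members, for mdx minus Control at left and mdx/miR-133b-/- minus mdx at right. Filled points passed an adjusted p of 0.05 by limma, open points did not, and bars are list medians; at left all 7 regenerating fibre genes lie above 0, and the horizontal ranges of the panels differ.

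In all, limma's test called 550 of the 831 genes at an adjusted p of 0.05, 370 higher and 180 lower, and 302 of them differed by more than 2-fold. The 4 values of one group lay wholly above the 4 of the other in 585 genes, where chance gives 23.7 (2.86%). In the set test camera, which asks whether a list moved more than the other listed genes, 4 lists passed: regenerating fibre (adjusted p = 0.0124), macrophage (0.000921), extracellular matrix (0.0124), and antigen presentation and complement (0.0141). None of them held with an estimated correlation between genes, where the adjusted p of each was 0.345. The slow fibre, fast fibre, neuromuscular junction, oxidative phosphorylation and glycolysis lists did not pass (adjusted p = 0.0917 each), nor did the fibro-adipogenic (0.125), tendon (0.116), atrophy (0.264), dystrophin complex (0.774) and miR-133 target (0.774) lists. With p-values adjusted over the list alone, the number of genes passing changed in 3 lists: 3 fast fibre genes fell instead of 2, no oxidative phosphorylation gene instead of 2, and Cpt2 instead of none.

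The share of genes called higher depended on the scaling. Upper quartile factors computed on the listed genes gave 554 calls, 62.6% of them higher, against 67.3% with the authors' factors. Relative log expression factors computed on the listed genes centre each library on its median listed gene. In a list where most genes differ this draws the calls toward an even split by construction. They gave 260 higher and 270 lower, against 370 and 180 with the authors' factors. The median log2 fold change of all listed genes moved from 0.44 to 0.09. Lama2, at 0.54 on the log2 scale, was then no longer called (0.18, adjusted p = 0.369), nor was it after removal of each library's trend with GC content and transcript length (0.29, 0.111). Ckm, at -0.45, and Ndufs1, at -0.42, lay near the threshold. The call of Ckm was lost with that trend removed (-0.35, adjusted p = 0.0694), without a variance trend in limma (-0.45, 0.0561), and without Control 1, 2 or 3 or mdx 1, 2 or 4 (-0.48 to -0.36, adjusted p from 0.0544 to 0.130), and that of Ndufs1 without Control 4 (-0.40, 0.0593) or mdx 3 (-0.41, 0.0524).

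Loss of miR-133b in muscle with dystrophin was assessed by comparing miR-133b-/- with Control. No listed gene passed. The listed genes all differ between mdx/miR-133b-/- and miR-133b-/-, which both lack miR-133b, so genes that respond only to its loss may be left out. The smallest p-values among higher genes belonged to Mdh2, a malate dehydrogenase (0.59 on the log2 scale, SE 0.17, adjusted p = 0.283), Efcab2 (0.76, SE 0.21, 0.272) and mt-Atp6, a mitochondrially encoded subunit of ATP synthase (0.93, SE 0.25, 0.272). Among lower genes they belonged to Fam129b (-0.97, SE 0.25), Vash2 (-1.24, SE 0.32) and Trp53i11 (-1.04, SE 0.29), each with an adjusted p of 0.272. mt-Atp6 stood at 143 ± 37.0 scaled reads in Control and 271 ± 46.0 in miR-133b-/- (SD, n = 4 each), and Vash2 at 93.8 ± 19.4 and 41.2 ± 19.3. These are few reads for a mitochondrially encoded gene here: mt-Nd2 stood at 84577 to 142191 in the Control libraries.

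No member of any of the 17 lists with listed genes passed in this comparison, over all genes or adjusted over the list alone, and no list passed the set test (smallest adjusted p = 0.371). The macrophage genes had a median log2 fold change of -0.17, the extracellular matrix genes -0.28, and the 7 regenerating fibre genes -0.63. limma called 0 of 831 genes, with 84 at an unadjusted p under 0.05, where 41.6 would be reached by chance in genes not selected on the miR-133b-/- libraries; limma-voom on the reads also called 0. In simulated data with a spread pooled over the 4 groups and 200 changed genes per run, the test recovered 26.4% of 1.5-fold and 66.4% of 2-fold changes. Where few genes change the adjustment is stricter, so these shares may overstate what could be found here. Of the listed genes 748 differed by less than 1.5-fold in this comparison. The replicates of miR-133b-/- varied more than those of Control, as given above.

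In mdx muscle, the question was what the loss of miR-133b adds, tested by comparing mdx/miR-133b-/- with mdx. The largest rises by the naming rule were in Rp2 (2.83-fold, SE 0.23 on the log2 scale), Svbp (1.44 on the log2 scale, SE 0.27), Crebzf (1.36, SE 0.23) and Arntl (1.30, SE 0.23). Rp2 encodes a protein of the cilium, Svbp a partner of vasohibins, Crebzf a transcriptional regulator, and Arntl (also known as Bmal1; chromosome 7, 113207465 to 113314126) a core activator of the circadian clock. Arntl stood at 168 ± 42.1 scaled reads in mdx and 418 ± 109.5 in mdx/miR-133b-/- (SD, n = 4 each). The largest falls were in Dbp (-1.93, SE 0.29), Paqr4 (-1.80, SE 0.28), Mien1 (-1.58, SE 0.24) and Tmem267 (-1.46, SE 0.42). The rule leaves out means under 50, predicted models and genes whose groups overlap. Outside it, Zfp970 (-5.55, SE 0.38) and the models Gm14325, Gm14326, Gm14403 and Gm47283 fell further, Ighm fell by 1.64, and the models Gm8822 (3.53) and Gm4841 (1.64) rose by more than Rp2. Dbp, a circadian transcription factor on chromosome 7 (45705088 to 45710203), dropped from 1006 ± 89.8 to 279.7 ± 120.4 scaled reads (adjusted p = 0.000236).

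Fast-fibre genes were lower in the double mutant: Actn3, Pvalb and Ckm fell, and Myh4 (-0.56, adjusted p = 0.138) did not pass, although all 4 passed when adjusted over the list alone. Actn3, a fast-fibre actinin, went from 56348 ± 11247 to 29857 ± 3625 scaled reads. Of 4 listed oxidative phosphorylation genes Cox5a (-1.07, SE 0.22) and Atp5a1 fell. Nos1, the neuronal nitric oxide synthase bound to the dystrophin complex, fell by 0.73 (SE 0.22) and was the only one of 3 listed members of that list to pass. Runx2 (0.98, SE 0.30) was the only one of the 4 listed miR-133 targets to pass, and Lox, a collagen crosslinking enzyme (1.22, SE 0.34), the only one of 9 extracellular matrix genes. None of the 13 macrophage, 7 regenerating fibre, 5 antigen presentation, 5 neuromuscular junction, 4 slow fibre or 3 glycolysis genes passed, nor did those of the fibro-adipogenic, tendon, atrophy, interferon, endothelial and fatty acid lists. The median log2 fold change of the macrophage genes was 0.00 and that of the regenerating fibre genes -0.38. It was -0.73 for the antigen presentation genes, -0.42 for glycolysis, -0.37 for slow fibre and 0.10 for neuromuscular junction genes.

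limma called 162 genes here, 62 higher and 100 lower, of which 49 differed by more than 2-fold, and the groups did not overlap in 221 genes. Unselected genes would give 23.7 by chance, but genes selected on the mdx/miR-133b-/- libraries separate more often without any effect. No list passed camera; the fast fibre list came nearest (adjusted p = 0.0763, and 0.910 with an estimated correlation). The 162 calls lay at opposite ends of GC content: the higher genes had a median of 43.6% GC and the lower ones 53.7%, and their median transcript lengths were 4806 and 2309 bases. Across the 831 genes, which are not independent replicates, the log2 fold change correlated with GC content at a Spearman rho of -0.49, against -0.22 for miR-133b-/- minus Control and -0.08 for mdx minus Control.

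The number of calls depended on the libraries used and on this trend. It fell to 49 without mdx/miR-133b-/- 4, to 70 without mdx/miR-133b-/- 3, and to 71, 56 and 84 without mdx 1, 3 and 4. Without mdx 2 it was 111 and without mdx/miR-133b-/- 2 it was 126, while without mdx/miR-133b-/- 1 it rose to 197. Part of a fall can come from the smaller group. After removal of each library's linear trend with GC content and length, 55 genes passed. Of the genes named, Actn3 lost its call without mdx 3 (-0.80 on the log2 scale against -0.90, adjusted p = 0.06), Lox without mdx 2, mdx 4 or mdx/miR-133b-/- 4 (0.80 to 1.13 against 1.22, 0.0506 to 0.0794), and Tmem267 without mdx 2, mdx 3 or mdx/miR-133b-/- 2 (-1.39 to -1.28 against -1.46, 0.0507 to 0.0741). Nos1 lost it without mdx 1, 3 or 4 or mdx/miR-133b-/- 3 or 4 (-0.76 to -0.61 against -0.73, 0.0527 to 0.0887), and Runx2 without mdx 1, 2 or 3 or mdx/miR-133b-/- 3 or 4 (0.88 to 0.96 against 0.98, 0.0649 to 0.09). With the GC and length trend removed, the log2 fold change of Actn3 went from -0.90 to -0.58 (adjusted p = 0.0952), that of Lox from 1.22 to 0.93 (0.0735) and that of Runx2 from 0.98 to 0.85 (0.0694), and none of the 3 passed, while Arntl (0.0025) and Dbp (0.0246) did.

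**Figure D2:**
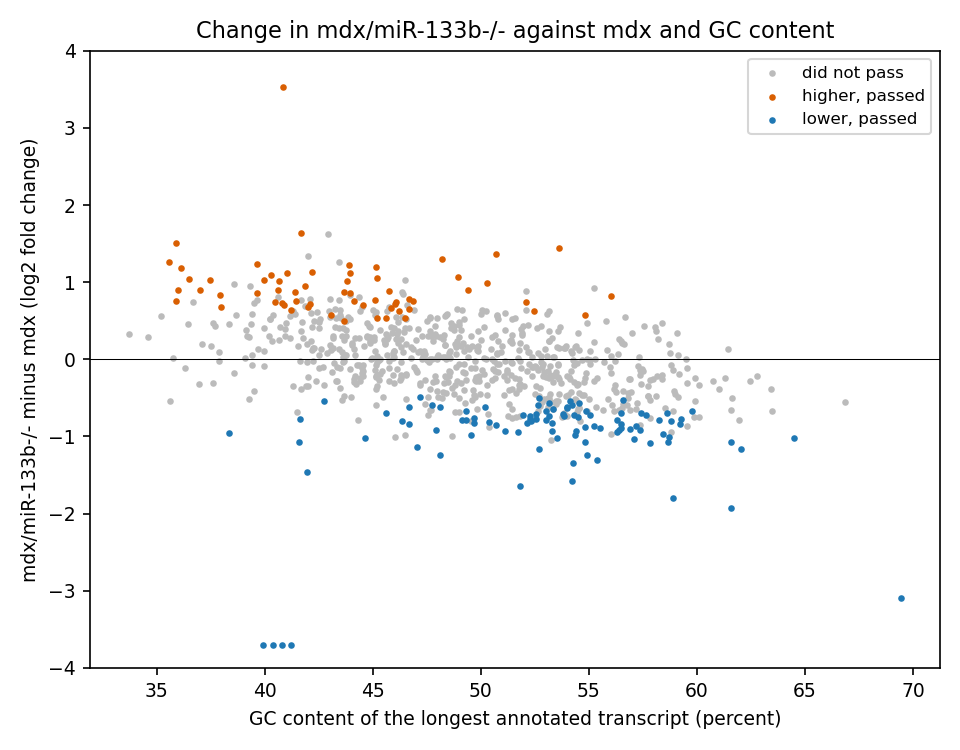
Log2 fold change of mdx/miR-133b-/- minus mdx (vertical axis) against the GC content in percent of each gene's longest annotated transcript (horizontal axis), with the 62 higher and 100 lower genes that passed in colour and the others in grey. Higher genes lie mostly to the left (median 43.6% GC) and lower genes to the right (53.7%); 4 genes of chromosome 2 that fell further are drawn at the edge, at -3.7.

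Genes with a 3' UTR match to the seed of miR-133b were set against genes without one. Of 780 listed genes with an annotated 3' UTR, 89 had a match to positions 2 to 8 of the microRNA. Their median log2 fold change in mdx/miR-133b-/- against mdx was 0.10, against -0.08 for genes without a match, a difference of 0.19 that did not pass camera (p = 0.0688, and 0.311 with an estimated correlation). The 25 genes with an 8mer match stood 0.34 above those without (camera p = 0.00251, and 0.0636 with an estimated correlation), or 0.24 with the GC and length trend removed (p = 0.0559); 5 of them were called higher and 1 lower. In miR-133b-/- against Control the medians were -0.10 and -0.07 (p = 0.25, and 0.517 with an estimated correlation), and the 25 genes with an 8mer match differed from those without by -0.05 (camera p = 0.996), or -0.02 with the GC and length trend removed (p = 0.972). Of genes with a match, 10 were called higher and 6 lower in the double mutant.

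The effect of mdx was measured in separate libraries on each background, since mdx minus Control and mdx/miR-133b-/- minus miR-133b-/- share none. Across the 831 genes, which are not independent replicates, the log2 fold changes correlated at a Pearson r of 0.88 and a Spearman rho of 0.91, and 809 had the same sign. Myh3 stood at 5.54 and 4.82, Atp6v0d2 at 4.88 and 5.84, and Ces1d at -2.95 and -3.27. Both tests called 370 genes higher and 179 lower, where independent lists of these sizes would share 221.7 and 72.1. Since the second test called all 831 genes, this overlap only restates the agreement in sign of the genes called by the first. A single gene passed in opposite directions, the processed pseudogene Gm8822 on the X chromosome. The log2 fold changes for loss of miR-133b on the 2 backgrounds correlated at an r of 0.08 (jackknife SD 0.21) and a rho of 0.14, with 441 genes of the same sign. The floor on the difference between mdx/miR-133b-/- and miR-133b-/- favours a high r in the first pair and can lower that in the second, where each difference holds 1 of these groups, so the 2 correlations cannot be set against each other.

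**Figure D3:**
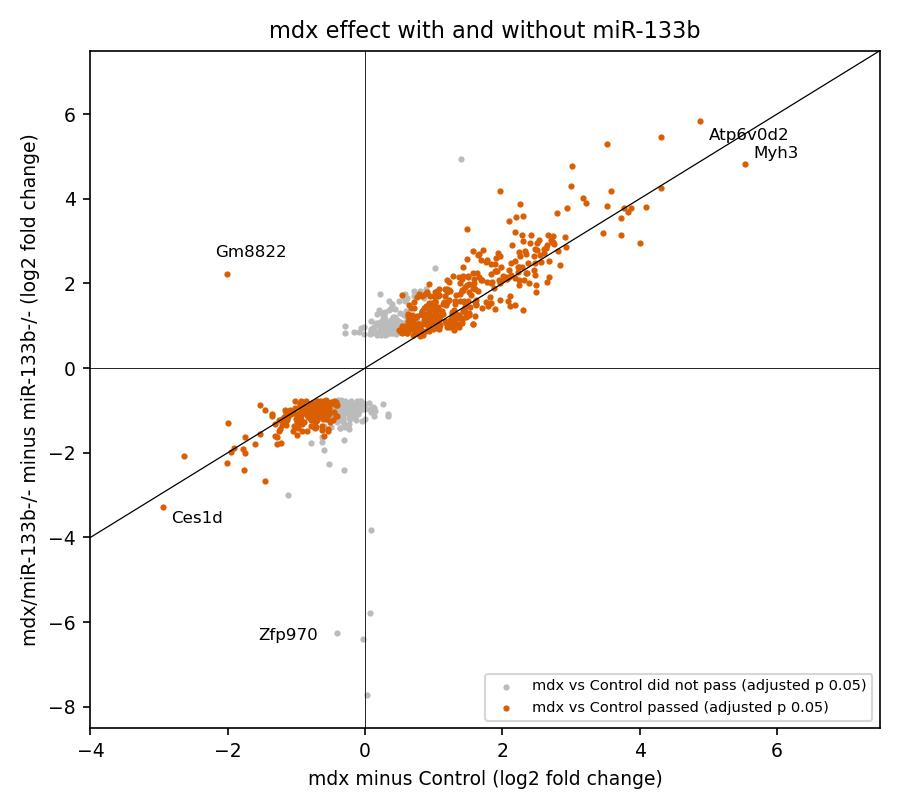
Log2 fold change of mdx/miR-133b-/- minus miR-133b-/- (vertical axis) against that of mdx minus Control (horizontal axis), 1 point per listed gene, with the diagonal marking equal values. Orange points passed in mdx minus Control; no point lies near 0 on the vertical axis because every listed gene differed by at least 1.72-fold there, and Gm8822 and the chromosome 2 genes around Zfp970 lie far from the diagonal.

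The double mutant was also set against Control and against miR-133b-/-. Compared with Control, all 13 macrophage genes, 6 of 7 regenerating fibre genes, 8 of 9 extracellular matrix genes, all 5 antigen presentation genes, all 4 slow fibre genes, 4 of 5 neuromuscular junction genes, and both genes of each of the fibro-adipogenic, tendon and atrophy lists rose, as did Oas2. All 4 fast fibre, all 4 oxidative phosphorylation and all 3 glycolysis genes fell, as did Cpt2 and Flt1. In the dystrophin complex list Sntb1 and Lama2 rose and Nos1 fell, and among the miR-133 targets Runx2, Gli3 and Egfr rose and Klf15 fell. Among the genes covered by the naming rule, which leaves out predicted models such as Gm14325, Gm14326 and Gm14403, Atp6v0d2 (5.06 on the log2 scale, SE 0.91), Mmp12, a macrophage metalloproteinase (4.84, SE 1.0), and Myh3 (4.84, SE 0.62) led the rises, and Zfp970 (-5.96, SE 0.38), Ces1d (-2.84, SE 0.54) and Ighm, the constant region of IgM (-2.77, SE 0.55), the falls. The fitted value of Zfp970, with 1 read per library in the double mutant, depends on the pseudocount, and the 3 models stood at -7.30, -5.88 and -6.01. Of the 831 genes 758 passed, 451 higher and 307 lower, or 323 and 332 with the relative log expression factors. Upper quartile factors gave 756 calls, 58.2% of them higher. Counts adjusted over the list alone were the same in all 17 lists, and only the macrophage list passed camera (adjusted p = 0.00737, and 0.376 with an estimated correlation).

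Compared with miR-133b-/-, all 831 genes passed, 498 higher and 333 lower, a count set by how the listed genes differ in this comparison. The relative log expression factors left 638, 305 higher and 333 lower, while upper quartile factors left all 831. With predicted models again left out, among the largest values were Atp6v0d2 at 5.84 (SE 0.91) and Mmp12 at 5.46 (SE 1.0), and at the other end Zfp970 at -6.27 (SE 0.38), Ces1d at -3.27 (SE 0.54) and Ighm at -3.01 (SE 0.55). The macrophage list again passed camera (adjusted p = 0.0183, and 0.405 with an estimated correlation), and no other list did.

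Whether the effect of losing miR-133b differed between dystrophic and other muscle was tested as an interaction. It was called in 8 genes, 7 negative and 1 positive. Dbp stood at 0.18 on the log2 scale in miR-133b-/- against Control, which did not pass, and at -1.93 in mdx/miR-133b-/- against mdx, a difference of -2.11 (SE 0.41, adjusted p = 0.00641). Gtf3a, a transcription factor for 5S ribosomal RNA, had a difference of -1.21 (SE 0.29, adjusted p = 0.0479). Zfp970, a zinc finger gene of chromosome 2 (177464733 to 177478129), was at 101 ± 31.8 scaled reads in Control, 128 ± 47.5 in miR-133b-/- and 76.0 ± 21.9 in mdx but at 0.589 ± 0.0956, or 1 read per library, in mdx/miR-133b-/- (SD, n = 4 each). The rest were predicted models: Gm14403, Gm14325 and Gm14326 of the same chromosome 2 segment as Zfp970, Gm8822, and Gm47283 on the Y chromosome, for which the sex of the animals is not given in the sources used here.

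By list, no gene passed over all genes, and adjusted over the list alone 1 dystrophin complex gene and 1 oxidative phosphorylation gene did; no list passed camera (smallest adjusted p = 0.317). At an unadjusted p under 0.05 there were 172 genes; the 41.6 that chance gives holds for unselected genes, and the listed ones were selected on 2 of the 4 groups. The call of Dbp was lost after removal of the GC and length trend, where its difference went from -2.11 to -1.63 (adjusted p = 0.179). That of Gtf3a was lost there as well (-0.85, adjusted p = 0.179) and in most of the other settings tried, at -1.27 to -1.08 against -1.21. Without miR-133b-/- 2 the count rose to 110 and without mdx/miR-133b-/- 1 to 15, and relative log expression factors gave 14.

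**Figure D4:**
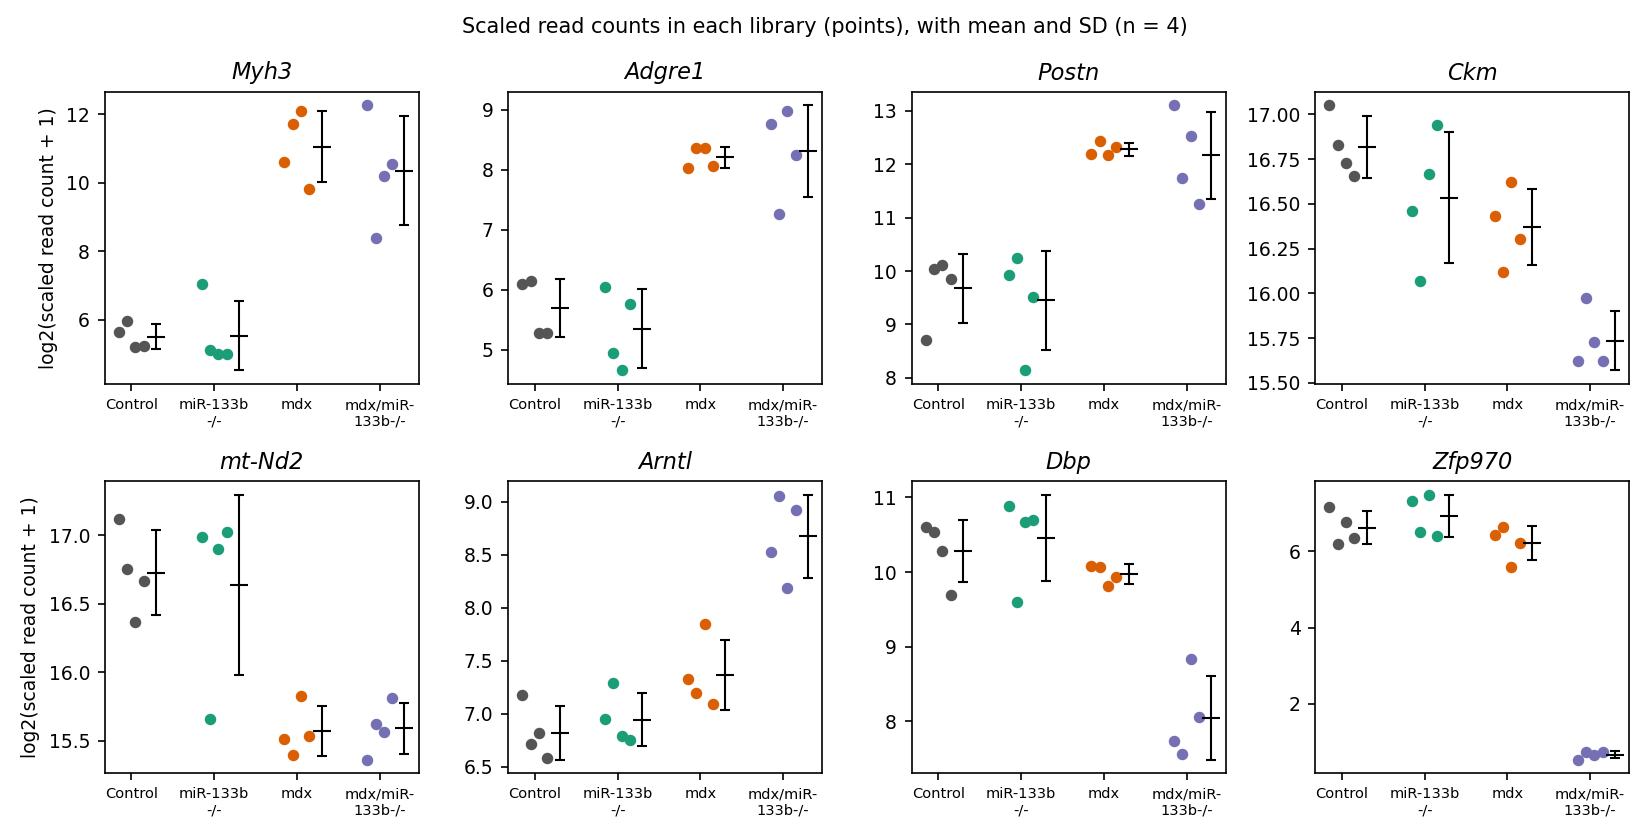
Scaled reads of 8 genes on a log2(value + 1) scale (vertical axes, which differ between panels and do not start at 0) in each library (points), with the mean and SD of each group beside them (n = 4); mt-Nd2 was chosen after its values were seen. The mdx and mdx/miR-133b-/- libraries lie above the others for Myh3, Adgre1 and Postn, Arntl and Dbp set mdx/miR-133b-/- apart, and Zfp970 is near 0 in its 4 libraries.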

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

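The tests of the chromosome 2 genes and of the clock genes below, and the list of clock genes, were chosen after their values were seen. Dixon's test for a library far from its group was applied to 134 groups and picked out 6, where chance gives 6.7. Tnni1 was at 2.86 scaled reads in Control 1 and 16.4 to 18.7 in the other Control libraries (gap over range 0.926). Runx2 was at 120.1 in mdx 4 and 83.8 to 88.8 in the others (0.838). Vash2 was at 70.1 in miR-133b-/- 4 against 29.98 to 33.8 (0.859), and mt-Atp6 at 339.7 in the same library against 245 to 249 (0.949). In miR-133b-/- 2, Dbp was at 776 against 1624 to 1883 (0.833), and Myh4 took 9.03% of the listed reads against 14.0% to 14.9% (0.852).

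The effect of mdx differed between backgrounds, by limma's interaction test, in 8 genes. The differences on the log2 scale were -1.21 for Gtf3a (adjusted p = 0.0479), -2.11 for Dbp (0.00641), -5.86 for Zfp970 (3.39e-07), -5.85 for Gm14403 (3.09e-06), -7.75 for Gm14325 (2.55e-08), -6.37 for Gm14326 (3.09e-06), -3.91 for Gm47283 (0.016) and 4.23 for Gm8822 (0.00224). Without miR-133b-/- 2 the interaction called 110 genes in place of 8, and without mdx/miR-133b-/- 1 it called 15. Gm14325 was listed at 0 in all 4 mdx/miR-133b-/- libraries, so its fitted value depends on the pseudocount. Gm47283, on the Y chromosome (90784738 to 90816464), had means of 111 in Control, 162 in miR-133b-/-, 93.1 in mdx and 13.4 in mdx/miR-133b-/-; the sex of the animals is not given in the sources used here.

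Zfp970, Gm14403, Gm14325 and Gm14326 lie in 1 segment of chromosome 2 (177464733 to 177957297), with gaps between them, the longest from 177509763 to 177831791. Their summed means were 477 scaled reads in Control, 644 in miR-133b-/-, 438 in mdx and 2.62 in mdx/miR-133b-/-, where no value exceeded 5.50, while the lowest value elsewhere was 34.3. Loss of miR-133b alone is argued against by a median log2 fold change of 0.37 for the 4 genes in miR-133b-/- against Control, and a shift of reads among the 4 by a sum in the double mutant of 0.599% of that in mdx. The first reading covers these 4 genes only, since genes lowered alike in miR-133b-/- and mdx/miR-133b-/- could not have been listed. A strain variant or deletion of the segment in the double-mutant line may be a candidate explanation: all 4 listed genes were under 10 in each of its libraries, but only genes that differ there are listed, so this test could not have come out otherwise. The strains of the lines are not given in the sources used here, and reads lost between these near-identical genes and copies outside the table were not tested.

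Of 6 listed clock genes, 3 passed between mdx/miR-133b-/- and mdx: Arntl rose by 1.30 on the log2 scale, and Dbp fell by 1.93 and Per2 by 0.98 (adjusted p = 0.0439). A linear trend with GC content and length as the cause of all 3 is argued against, since 2 of them still passed after its removal. These were Arntl at 1.22 (adjusted p = 0.0025) and Dbp at -1.32 (0.0246), while Per2 was at -0.94 (0.0956). A bias of another shape was not tested. A different time of day of sampling could move Arntl against the genes that peak opposite to it, but the 5 listed ones had a median of -0.38, with Hlf at -0.38, Ciart at 0.10 and Usp2 at 0.16 not passing, which decides nothing. Times of sampling are not given in the sources used here, and loss of miR-133b in dystrophic muscle stays open as untested. In mdx against Control, Hlf fell by 1.46, Ciart by 1.96 and Usp2 by 0.73, and Arntl was at 0.54 (adjusted p = 0.0479) but at 0.49 and no longer past the threshold with the trend removed (0.0677), while Dbp at -0.31 (0.340) and Per2 at -0.60 (0.113) did not pass.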

How the results depend on the processing

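The pseudocounts, the fit without a variance trend, the minimum mean of 100, the removal of GC and length trends and the 8mer test with that trend removed were chosen after seeing the data; the other settings were planned. limma called 550 genes in mdx against Control, and 530 to 554 with other scaling, 550 to 552 with other pseudocounts, 550 by limma-voom, 646 on the libraries of the 2 groups alone, 532 with the GC and length trend removed, and 474 to 578 when 1 library was left out. The mean minimum left 634 genes to test, of which 395 passed. In miR-133b-/- against Control every one of these settings, and each left-out library, gave 0. For mdx/miR-133b-/- against mdx the 162 calls became 120 to 173 with the other settings and 49 to 197 with 1 library left out, and 55 (20 higher, 35 lower) with the GC and length trend removed, of which 49 were calls before. For mdx/miR-133b-/- against Control (758) leaving out libraries gave 718 to 771, and against miR-133b-/- (831) 829 to 831; the mean minimum gave 583 and 634, and removal of the trend 661 and 733, with 12 and 9 of the calls changing sign. The 8 interaction calls became 14 (1 higher, 13 lower) with relative log expression factors, 4 with the mean minimum, 5 with the trend removed, and 7 to 110 with 1 library left out. Fewer genes tested accounts for part of the change under the mean minimum; elsewhere the cause was not tested.

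Relative log expression factors moved the median log2 fold change of all listed genes from 0.73 to 0.33 in mdx/miR-133b-/- against Control and from 0.95 to 0.39 against miR-133b-/-. Lists past the threshold numbered 4 in mdx against Control (4 to 5 with 1 library left out), 0 in miR-133b-/- against Control (0 to 1), 0 in mdx/miR-133b-/- against mdx (0 to 1) and 0 in the interaction (0 to 2). With an estimated correlation none passed in any comparison. For mdx/miR-133b-/- against Control, 1 list passed (1 to 5 with 1 library left out), 2 with relative log expression and 4 with upper quartile factors. Against miR-133b-/- it was 1 (1 to 5), 3 with relative log expression factors and 3 with the mean minimum. The correlation of the mdx effect between backgrounds was 0.86 to 0.89 with 1 library left out, and that of the miR-133b effect -0.07 to 0.19. Genes with an 8mer seed match stood 0.34 above those without in mdx/miR-133b-/- against mdx (p = 0.00251, and 0.0636 with an estimated correlation), 0.24 with the GC and length trend removed (p = 0.0559), and genes with any match 0.13 after adjustment for 3' UTR length and GC (p = 0.311).

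Replicate numbers did not pair the libraries: 2 of 24 same-number pairs correlated above 0.1 (range -0.28 to 0.25), and 1 of 16 libraries correlated best with its own number. With the replicate number as a block, 541, 0, 120, 749 and 831 genes passed in the order above, 7 in the interaction (without Gtf3a, adjusted p = 0.0872), and 4 lists in mdx/miR-133b-/- against Control; Ckm did not pass in mdx against Control (0.0604).

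Grouping by the description text called 0 genes in each comparison and in the interaction, and reversed 36 named values; no other setting reversed one. In mdx against Control these were Hk2 0.27, Adgre1 -0.41, Myh3 -0.76, Thbs4 -0.17, Cd74 -0.18, Ms4a7 -0.29, Slc1a1 0.25, Postn -0.24, Pdgfra -0.13, Flt1 0.23, Ckm 0.0452, Itgax -0.47, Oas2 -0.0598, Ciart 0.80, Ces1d 0.35, H2-Eb1 -0.18 and Myl4 -0.58. In miR-133b-/- against Control they were Mdh2 -0.12, Efcab2 -0.0518, Fam129b 0.12, Vash2 0.0271 and Trp53i11 0.24. In mdx/miR-133b-/- against mdx they were Cox5a 0.25, Mien1 0.19, Actn3 0.0446, Paqr4 0.16, Runx2 -0.0325, Crebzf -0.0392 and Arntl -0.0706. The rest were Myh3 -1.24 and Atp6v0d2 -0.58 against Control, Ces1d 0.49 and Ighm 0.23 against miR-133b-/-, and Gtf3a 0.22, Dbp 0.0773 and Zfp970 0.15 in the interaction. That setting mixes the groups by construction. With 1 library left out, 939 named values kept their direction and side of the threshold and 37 lost their call. Not run were the planned count models, in whose place limma-voom was run on the recovered reads, trimmed-mean factors, the read-per-million filter, which needs library totals, and the sex covariate, whose genes were not analysed here; a test without a filter is the one reported. Reads in listed genes limit the precision of low genes, and total depth is unknown.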

Other observations

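The gene groups in this part, the check of GC content and the test of seed matches as an explanation were chosen after the data were seen; the tests of a shared library axis, of the direction of selection and of the splits were written before, but the reading of the direction of selection as open, past its bound, was decided after. The first 5 groups hold members picked by hand, other listed genes of the same kinds lie outside them, and no set test is given for them. In mdx against Control, the 15 innate immune receptors picked rose, by a median of 2.35 on the log2 scale, 14 of them also with the GC and length trend removed. Outside this group Siglec1 (2.19) and Cd33 (1.64) also rose, and Mrc1 (0.33, adjusted p = 0.234) did not pass. Among the 15 were Clec7a (3.87), C3ar1, a complement receptor (3.53), and Tlr7 (2.61). The 12 lysosomal genes picked rose, including the protease genes Ctsk (1.58) and Lgmn (1.27). The 9 metalloproteinases and inhibitors picked rose by a median of 1.61, Mmp12 by 4.32 and Mmp13 by 3.23; outside them Adamts5 (0.78) and Adamts7 (0.99) rose and Adamts4 (1.40, adjusted p = 0.14) did not pass. Of 9 imprinted genes picked 7 rose, with a median of 1.28, among them Igf2 (1.76), a fetal growth factor, and Peg3 (1.16). The 4 genes picked from serine and asparagine synthesis and its regulators rose (median 1.15), with Phgdh at 1.43 and Asns at 1.29. With the GC and length trend removed 3 of them passed.

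All 9 listed mitochondrially encoded transcripts fell in mdx against Control (camera, adjusted p = 3.12e-05 over the 7 groups of this part, and 0.234 with an estimated correlation), 8 of them also with the GC and length trend removed. mt-Nd5, a subunit of respiratory complex I, went from 252176 ± 64945 to 120995 ± 7409 scaled reads (SD, n = 4 each), a fall of 1.02 on the log2 scale. Their share of listed reads was 33.7% ± 3.89 in Control, 34.0% ± 3.76 in miR-133b-/-, 25.2% ± 1.76 in mdx and 28.9% ± 4.93 in mdx/miR-133b-/-. In mdx/miR-133b-/- against mdx none of them fell, and mt-Tw (1.09) and mt-Atp6 (0.90) rose, but with the trend removed 1 of the 9 rose and 1 fell. The rise of mt-Atp6 rests on few reads. It stood at 65.8 ± 18.0 scaled reads in mdx and 122 ± 22.9 in mdx/miR-133b-/-, against 120995 for mt-Nd5 in mdx. Of 10 listed nuclear genes of the respiratory complexes, 6 fell in mdx/miR-133b-/- against mdx, including Ndufb5 (-1.24), Cox5a (-1.07) and Ndufs8 (-0.88). Once the GC and length trend was removed, 3 passed. The median of the 10 was -0.73 (camera, adjusted p = 0.000422, and 0.752 with an estimated correlation). All 10 also fell against miR-133b-/-, the difference that every listed gene shows. That favours a fall in the same double-mutant libraries, so the set test decides nothing here. The fixed oxidative phosphorylation list, whose 4 listed members are in this group, did not pass camera in mdx/miR-133b-/- against mdx (adjusted p = 0.129).

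The genes called between mdx/miR-133b-/- and mdx followed GC content and transcript length, with GC slopes of -0.30 ± 0.21 log2 units per 10 points in mdx/miR-133b-/- and 0.07 ± 0.07 in mdx, and -0.28 in miR-133b-/- 1 (SD, n = 4 each; exact permutation p = 0.0286, the smallest this design can give, adjusted 0.0714). A linear trend of this kind as the cause of all calls is argued against, since 49 of 162 (30.2%) passed in the same direction after its removal. The bound for this reading was set knowing that count. A bias of another shape could leave such calls and was not tested, so bias in general stays open. The median size of the 162 went from 0.83 to 0.54 and their median SE from 0.23 to 0.20. Of the 113 lost calls 112 had a smaller fold change. An unadjusted p beyond any called before was found in 88, and 25 had a p that would have passed before, lost to the stricter adjustment. As the cause of part of the calls, a GC and length bias cannot be told apart from biology. The main axis of replicate differences within Control and miR-133b-/- correlated with the change at a rho of -0.32, past the bound of 0.3 written before. That axis correlated at only -0.06 with GC content, and the reading of that outcome as open was decided after it was seen. Selection of the listed genes stays open: 154 of the 162 calls (95.1%, against 72.0% of all listed genes) moved in the direction of their difference from miR-133b-/-, but both differences share the mdx/miR-133b-/- libraries, which raises such a share without any selection. Loss of miR-133b through seed matches stays open, with a camera p of 0.0688 for any match (0.311 after adjustment for 3' UTR length and GC) and of 0.00251 for 8mer matches (0.0636 with an estimated correlation, 0.0559 with the trend removed), against 0.996 for 8mer matches in miR-133b-/- against Control. The last value cannot weigh against it, since genes raised alike in both groups that lack miR-133b may be left out of the listed genes.

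Splits of the same libraries tested whether a chance assignment of samples calls as many genes. For mdx against Control only 1 of the 35 splits, the real one, called as many as 550 genes, and the highest other called 0. Chance is argued against there, where the floor found in the listed genes involves neither group, but 1 of 35 is the smallest share these splits can give. It was also 1 of 35 for mdx/miR-133b-/- against mdx (162 against 2), against Control (758 against 40) and against miR-133b-/- (831 against 288). Selection on the libraries of the double mutant favours the real split in these 3 comparisons, and sets the count in the last, so the splits leave chance open there. In miR-133b-/- against Control no split can call fewer than the 0 found, so that all 35 reach it and the test decides nothing; the highest called 8. For the interaction 3 of 100 draws reached 8 genes, the real one included, a share under 0.05, but the same selection applies. The highest other draw called 92, several times the real count, and kept the real labels of the mdx and mdx/miR-133b-/- libraries. Of the 99 other draws 3 left the mdx and mdx/miR-133b-/- libraries as labelled, so that the difference between these groups stayed in, and both that reached 8 were among them; the highest of the rest called 1.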
